A study of Ovis aries with 7 samples.

How the data were processed

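PolyA RNA from sheep embryos at the 8-cell stage was amplified for 20 PCR cycles and sequenced as paired 150-nucleotide reads with Smart-seq2, per the labels' protocols. Labels name 3 IVF and 4 SCNT samples. The protocols mention independent trials per group without tying a library to a trial, and the number of embryos per library is not given in the sources used here, so the spread between libraries may be partly technical. The deposited table holds TPM for 31304 rows and 7 columns, and each column used sums to 1000000. The authors trimmed with fastp 0.23.4 and aligned with HISAT2 2.2.1, per the submitters' processing notes. Those notes name mouse and pig genome builds. The sheep build, the annotation and the counting tool are not given in the sources used here. TPM divides by gene length and by the library total, so a rise in abundant genes lowers the others, and depth cannot be recovered.

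Columns were assigned to samples by name only. The names of 3 columns match the IVF samples, and 4 columns of per-sample values match no sample label and were not used. The comparison of SCNT with IVF, planned before the data were examined with limma and gene set tests on log2(TPM + 1), was therefore not made, and neither were the planned permutation tests between groups or the comparison of X-linked genes. Values in those 4 columns were seen while the table was inspected and are not used. All descriptions of IVF libraries alone were designed after the columns were known.

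Row names were taken as deposited, and 28875 of 31304 matched the ARS-UI_Ramb_v3.0 gene table, which supplied symbols for mitochondrial rows and showed which genes lie inside another gene. Its build may differ from that of the table, so no coordinates are given. A gene is called wholly inside another where overlapping genes, alone or together, cover its whole span. There were 16539 rows with a gene symbol, 12307 with only a LOC identifier and 2434 for tRNA, and 8611 rows were at 0 in all IVF libraries. Genes at 1 TPM or more were counted as detected. Log values are log2(TPM + 1), which understates ratios of low genes.

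The 31 gene lists were fixed before the data were examined. The level of a list is the median TPM of its members per library. Its percentile compares the median of the members' mean TPM with 10000 random lists of the same size drawn from symbol rows (seed 7), and describes these libraries without being a test. Lists share some members and are not independent. The background holds many silent genes, with a median mean TPM of 1.58, so a high percentile says only that a list lies above typical symbols. On simulated lists of 30 genes, 50 per setting drawn from the 16539 symbol rows and each set against 500 random lists, the level step passed the 95th percentile in 10.0% with no shift, 24.0% with a 2-fold shift and 94.0% with an 8-fold shift. The step for a difference between libraries draws random lists matched on mean TPM in 20 bins. It was tried on the 5778 symbol rows with a mean of at least 5 TPM. There it passed the 95th percentile in 2.0%, 100% and 100% of simulated lists at the same shifts. The differences in that trial were simulated as independent normal values of equal spread for all genes, not taken from the libraries. Real differences can vary together within a list and with level, so these rates may not hold for them. With 50 lists per setting, the rates of both steps are rough.

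The rule for naming genes relied on the planned comparison in 2 of its parts. The remaining part, a panel of 16 genes, was kept. Of these 12 are given, and KDM4E, DPPA3, XIST and H19 were not analysed here. In place of the other parts, genes came from the 15 most abundant symbols and from up to 4 of the most abundant members per list. A further 12 gene pairs, and single genes such as COL1A2, were chosen after their values were seen. Alternatives were other detection thresholds, pseudocounts, correlation measures, scalings (median of ratios, quantile normalization, removal of mitochondrially encoded and ribosomal protein genes) and leaving out each library. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.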

Results

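Messenger RNA was measured by polyA-selected Smart-seq2 sequencing of sheep (Ovis aries) embryos at the 8-cell stage. The design set embryos made by in vitro fertilization (IVF, 3 libraries) beside embryos made by somatic cell nuclear transfer (SCNT, 4 libraries), in which a somatic nucleus replaces that of the egg. The series title places the question in how unevenly cloned embryos are reprogrammed. Values used here belong to the 3 IVF libraries, and the SCNT libraries were not analysed here, because 4 columns of the table carry a name that no sample label uses. No difference between SCNT and IVF is therefore given, and what follows describes the level of genes and gene groups in IVF embryos. Values are TPM, which scales transcript abundance by gene length and library total, as mean ± SD with n = 3 unless said otherwise. TPM keeps no sequencing depth, so the depth is unknown and no interval or detection floor is given.

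The IVF libraries held 11090, 12246 and 10973 genes at 1 TPM or more, a mean of 11436 ± 704. Ranks of 9822 genes at 1 TPM or more in all 3 libraries correlated across genes with a Spearman coefficient of 0.893 between replicates 1 and 2, 0.939 between 1 and 3, and 0.938 between 2 and 3. Genes are not independent replicates, so no p-value is given for these coefficients. The most abundant gene with a symbol was CKS2, a small subunit that binds cyclin-dependent kinases, at 43394 ± 5000.5 TPM. The actin-binding peptides TMSB4X and TMSB10 reached 29857 ± 7722 and 7844 ± 994. Also among the 15 most abundant symbols were the ribosomal protein precursors FAU (12163 ± 1898) and RPS27A (7935 ± 1018), ubiquitin UBB (7079.6 ± 1439), the mitotic ubiquitin-conjugating enzyme UBE2C (6694 ± 1339.6), the initiation factor EIF1 (6716 ± 1071) and the histone variant gene H3F3A (5559 ± 1229.7). The 10 most abundant rows took 16.9 ± 1.36% of all TPM.

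Genes linked to genome activation, the switch from stored maternal RNA to transcription by the embryo, were abundant. In the list fixed for them, 27 of 30 members in the table had at least 1 TPM in all 3 libraries, and the median member stood at 62.5 ± 32.8 TPM. That level lay above all 10000 random lists of the same size drawn from gene symbols (percentile 100). Part of the list, EIF1AX, EIF5, SNRPD1 and PSMA6 included, also belongs to the initiation factor, spliceosome and proteasome lists, which were high too. No oocyte or earlier stage was measured, so the level does not separate stored maternal RNA from new transcription. The paired-like homeobox gene ARGFX was at 614 ± 355, the proteasome subunit PSMA6 at 1547 ± 417, the splicing protein SNRPD1 at 1113 ± 77.2 and the initiation factor EIF5 at 558 ± 38.2. KLF17 reached 107 ± 9.0 and EIF1AX 489 ± 44.6. ZSCAN4, a marker of early embryonic transcription, varied among libraries at 54.7, 216 and 69.3 TPM in replicates 1, 2 and 3. The list's median was 43.3, 100.3 and 43.8 TPM in the same order, so replicate 2 held the highest value.

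**Figure D1:**
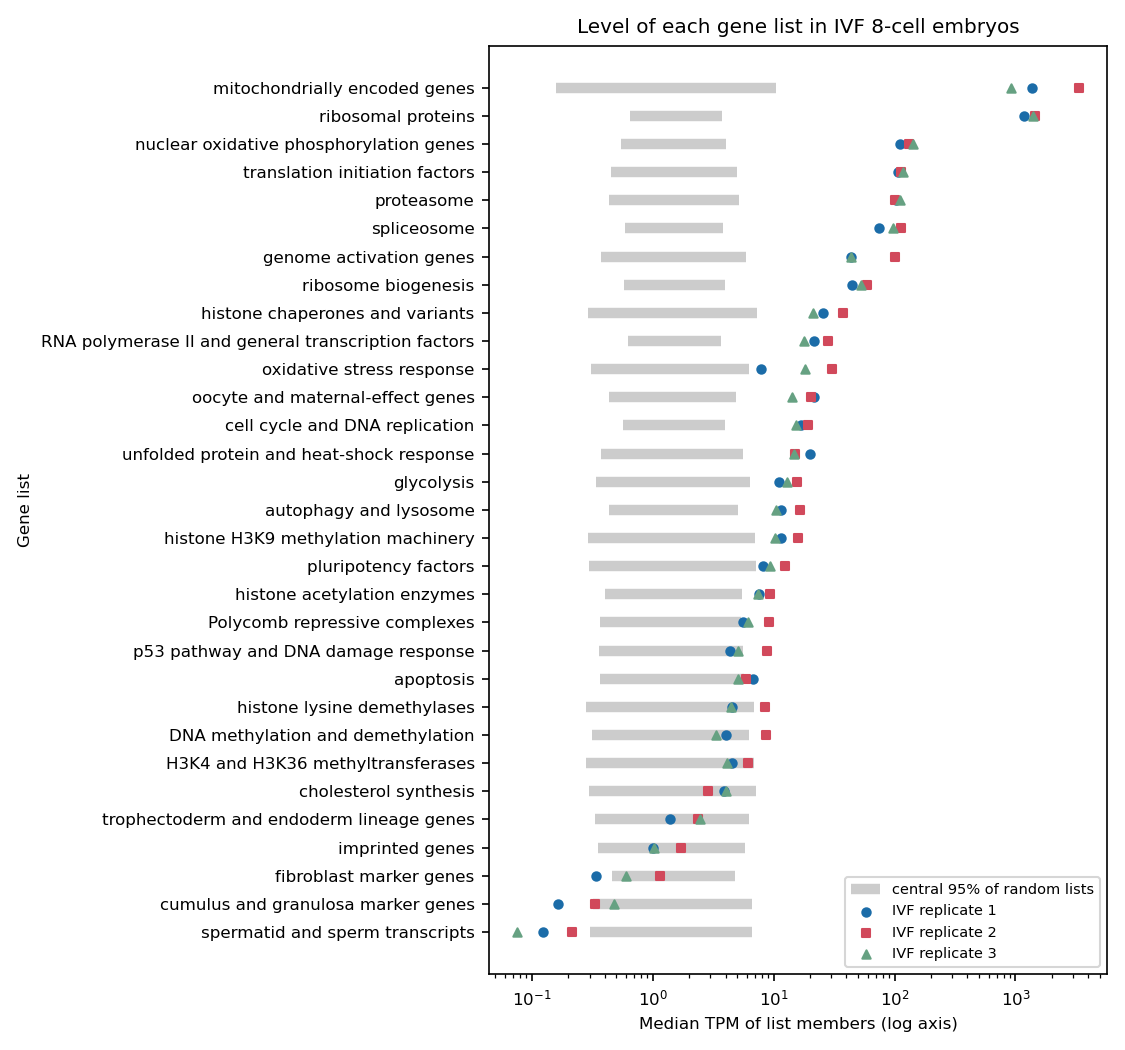
Median TPM of the members of each fixed gene list (log axis) in the 3 IVF libraries, 1 point per library. The grey bar is the central 95% of random lists of the same size. The bar was computed on mean TPM over the 3 libraries, so a single point against it is not the stated percentile. Mitochondrially encoded and ribosomal protein genes stand highest and spermatid and sperm transcripts lowest.

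Pluripotency factors were present, though POU5F1, SOX2 and NANOG were not the most abundant of them. Of the list, 18 of 22 members had at least 1 TPM in all libraries, with a median of 9.98 ± 2.2 TPM (percentile 99.65). PRDM14, KLF4, SALL4 and TCL1A led at 121 ± 39.0, 120.2 ± 28.9, 113 ± 48.6 and 68.6 ± 17.1 TPM. POU5F1, the central pluripotency regulator, was at 20.5 ± 3.38, SOX2 at 12.9 ± 2.09 and NANOG at 13.6 ± 7.29, with NANOG lowest in replicate 1 (5.20, 17.1 and 18.4 in replicates 1, 2 and 3). On the log2(TPM + 1) scale SALL4 exceeded POU5F1 by 2.33 ± 0.47 and KLF4 exceeded KLF2 by 6.08 ± 0.98, each in 3 of 3 libraries. Both pairs were chosen after their values were seen.

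Trophectoderm and endoderm genes, which mark the first lineages set aside later, were at the level of ordinary genes as a list, with a median of 2.07 ± 0.585 TPM (percentile 72.0) and 14 of 26 members at 1 TPM or more throughout. Single members were high. TFAP2C, a transcription factor also held by the genome activation list, was at 164, 692 and 299.8 TPM in replicates 1, 2 and 3, and ID2 at 266 ± 84.4. GATA6, a primitive endoderm factor, was at 46.2 ± 19.6 and exceeded GATA4 by 5.08 ± 0.74 on the log2(TPM + 1) scale, a difference of 3.20 with a pseudocount of 5. CDX2, a trophectoderm factor, was listed at 0 in all 3 libraries. Over all lists 28 members were listed at 0. Of these, 10 lie wholly inside another gene, among them RPL27 and PSMB6, which dividing cells use, and 18, CDX2 included, do not.

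RNA of genes known for their expression in the oocyte was plentiful. 36 of 41 members had at least 1 TPM in all libraries and the list's median was 18.8 ± 4.08 TPM (percentile 100). KPNA7, an oocyte importin, stood at 415 ± 116, the RNA decay adaptor BTG4 at 368 ± 121, the zona pellucida gene ZP4 at 319 ± 157 and the meiotic kinase MOS at 314 ± 167.

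Lists of markers of other cell types had low medians. With all libraries kept, only the spermatid and sperm list lay below the 5th percentile of random lists drawn from all symbols. Cumulus and granulosa markers had a median of 0.325 ± 0.156 TPM (percentile 6.33) with 6 of 24 at 1 TPM or more throughout, led by GATM at 46.2 ± 19.3 and the hyaluronan synthase HAS2 at 10.01 ± 3.00. Fibroblast markers had a median of 0.693 ± 0.408 TPM (percentile 8.46) with 17 of 43 at that level. S100A11 was the highest of them at 464 ± 84.3. Of the 43, 5 were at 10 TPM or more in all libraries and 4 were at 0 in all. FSTL1, for example, was at 35.2, 39.1 and 49.6 TPM in replicates 1, 2 and 3. VIM, the fibroblast intermediate filament, was at 7.90 ± 1.25. The collagen gene COL1A2 was at 0.582, 2.78 and 1.57 in replicates 1, 2 and 3. Spermatid and sperm transcripts were lowest of the 31 lists, at 0.138 ± 0.0699 TPM (percentile 0.650), although SPA17 was at 228 ± 23.6. With replicates 1, 2 and 3 left out in turn, the cumulus list was at percentiles 2.85, 8.11 and 5.63. The fibroblast list was at 17.0, 3.28 and 11.9 in the same order. The cumulus marker PTX3, listed at 0 in all libraries, lies wholly inside another gene. With such members left out, the cumulus list was at percentile 9.23 and the fibroblast list at 7.09.

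Enzymes that write, read or erase chromatin marks were expressed at uneven levels within families. The H3K9 methylation list had 20 of 22 members at 1 TPM or more and a median of 12.6 ± 3.04 TPM (percentile 99.66), with the heterochromatin proteins CBX3 and CBX5 at 143 ± 22.1 and 65.2 ± 8.92. SETDB1 was at 17.8 ± 5.26 against 3.96 ± 1.77 for SUV39H1, a log2 difference of 1.94 ± 0.25. Polycomb genes had a median of 7.0 ± 1.92 TPM (percentile 99.24), led by RBBP7 at 771 ± 69.4 and RBBP4 at 298 ± 118, and EZH2 exceeded its paralog EZH1 by 3.63 ± 0.37. Histone acetylation enzymes had a median of 8.11 ± 1.07 TPM (percentile 99.70), and HDAC2 at 269.9 ± 40.4 exceeded HDAC1 by 3.09 ± 0.43. All of these log2(TPM + 1) differences had the same sign in 3 of 3 libraries. The pairs were chosen after their values were seen, so that agreement is no separate support.

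DNA methylation genes had a median of 5.33 ± 2.90 TPM and histone lysine demethylases 5.79 ± 2.26, at percentiles 96.3 and 96.2. Both rested on replicate 2, and without it the percentiles were 87.2 and 93.1. With members wholly inside another gene left out, the DNA methylation list was at percentile 93.7. The maintenance methyltransferase DNMT1 was at 33.1 ± 5.36 TPM and the de novo enzyme DNMT3A at 9.48 ± 3.18. DNMT1 exceeded DNMT3A by 1.73 ± 0.22 and DNMT3A exceeded DNMT3B by 1.24 ± 0.56 on the log2(TPM + 1) scale, the latter a difference of 0.78 with a pseudocount of 5. The difference between TET1 and TET3, 0.93 ± 0.95, was smaller than its spread, and was 0.49 with a pseudocount of 5 and 0.43 without replicate 2. Among members of the demethylase list, RIOX2 was at 52.1 ± 7.20 and KDM1A at 29.8 ± 17.2. H3K4 and H3K36 methyltransferases stood at 4.91 ± 1.04 TPM (percentile 92.3), led by DPY30 at 207 ± 17.3. Histone chaperones and variants stood at 28.0 ± 8.32 (percentile 99.99), with H2AZ1 at 4418 ± 1790.4. Imprinted genes stood at 1.24 ± 0.407 (percentile 54.0, or 29.0 without replicate 2 and 30.7 against symbols above 0), with PHLDA2 highest at 122 ± 47.8.

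**Figure D2:**
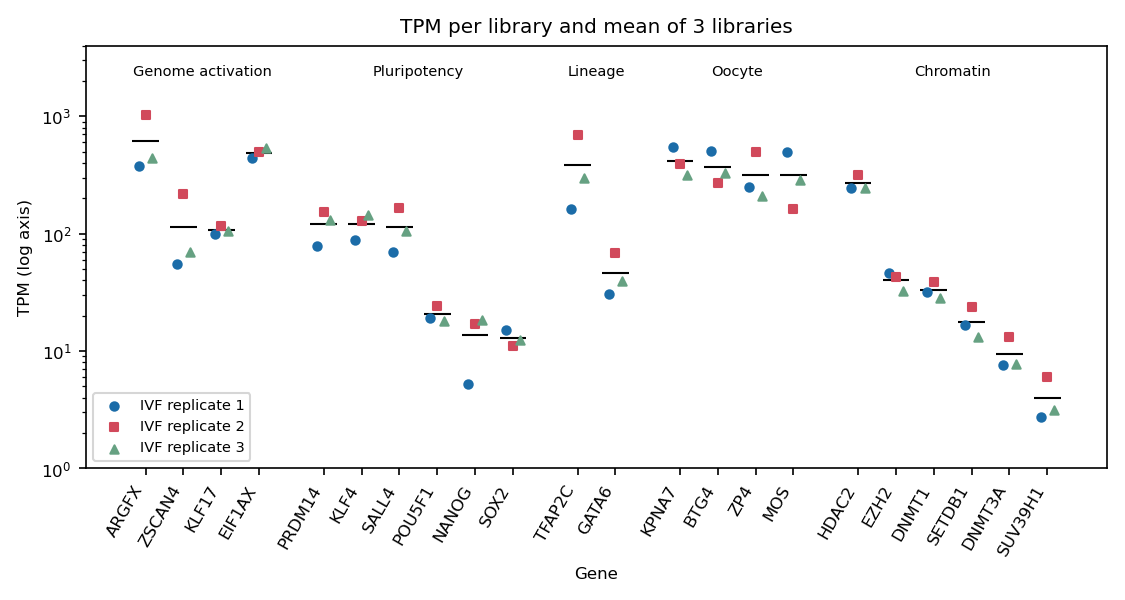
TPM of named genes (log axis) in the 3 IVF libraries, 1 point per library, with a horizontal line at the mean. SALL4 and KLF4 lie above POU5F1, NANOG and SOX2 in every library, and HDAC2 lies above the other chromatin genes drawn.

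Genes for making RNA and for making and degrading protein were abundant. Ribosomal proteins took 13.5 ± 1.02% of TPM with a median of 1347 ± 144 (percentile 100). Medians were 112 ± 4.76 TPM for translation initiation factors, 94.5 ± 18.8 for the spliceosome, 105 ± 5.24 for the proteasome, 52.0 ± 7.07 for ribosome biogenesis and 22.4 ± 5.23 for RNA polymerase II and general transcription factors. Each of these lay at percentile 100. The most abundant member of each was EIF1, given above, SNRPC (2273 ± 536), PSMB2 (1582 ± 344), NHP2 (699 ± 144) and POLR2F (1897 ± 385). Cell cycle and DNA replication genes had a median of 17.2 ± 2.03 (percentile 100), with the spindle checkpoint gene MAD2L1 at 1590.3 ± 636 and CDK1 at 632 ± 5.72. CKS2 exceeded its paralog CKS1B by 4.02 ± 0.24 on the log2(TPM + 1) scale.

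Energy genes were abundant, and their mitochondrial part was the least even. Mitochondrially encoded genes took 2.25, 4.88 and 1.66% of TPM in replicates 1, 2 and 3, a mean of 2.93 ± 1.72, with a list median of 1877 ± 1293 (percentile 100), or 1141 without replicate 2. CYTB of complex III was at 2393, 8899 and 1738 TPM in the same order. Nuclear oxidative phosphorylation genes had a median of 128 ± 16.3 (percentile 100), with NDUFA4 at 5116 ± 1251. Glycolysis genes had a median of 13.2 ± 2.34 (percentile 99.91). The glucose transporter SLC2A3 was at 281 ± 134 and exceeded SLC2A1 by 6.37 ± 0.55, and LDHA exceeded LDHB by 1.83 ± 1.12. Cholesterol synthesis genes stood at 3.59 ± 0.649 (percentile 85.8), yet MSMO1 was at 442 ± 35.1.

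Stress and apoptosis lists were mostly above the level of random lists. The apoptosis list holds genes that restrain cell death as well as genes that carry it out, so its level gives no direction. Medians were 16.6 ± 2.88 TPM for the unfolded protein and heat-shock response (percentile 100), 18.8 ± 11.3 for the oxidative stress response (percentile 100), 12.8 ± 3.21 for autophagy and lysosome (percentile 99.99) and 5.89 ± 0.805 for apoptosis (percentile 97.6). The chaperone gene DNAJB9 was at 666 ± 75.5, SOD1 at 690.3 ± 77.4, MAP1LC3B at 3173 ± 741 and BCL2L10 at 770.3, 210.1 and 364 in replicates 1, 2 and 3. The p53 pathway list stood at 6.06 ± 2.37 (percentile 98.0), which without replicate 2 became 94.3, with TRIAP1 at 381 ± 5.46 and PMAIP1 at 226 ± 29.6. In all, 24 of 31 lists lay above the 95th percentile of random lists, 1 below the 5th and 6 between. Against random lists drawn only from symbols above 0 in a library, the number above was 20, without DNA methylation genes, demethylases, the p53 pathway and apoptosis. With 3 libraries of a single kind no test between groups exists, and an exact two-sided sign-flip test of a gene pair could not give a p below 0.25.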

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

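A background of symbols above 0 in a library, the removal of list members lying wholly inside another gene, and all settings for replicate 2 were chosen after seeing the data. Other settings written beforehand for SCNT against IVF were not run, and no paired value exists. No paired analysis was possible because the values used belong to a single group. Genes detected per library went from 11436 at 1 TPM to 16877 at 0.1 TPM and 6870 at 5 TPM, as the threshold itself sets. The mean correlation between libraries, 0.923 by Spearman, was 0.952 by Pearson and 0.893 over genes with a mean of at least 5 TPM (the cause was not tested), and ranged from 0.893 to 0.939 when each library was left out, lowest without replicate 3, where only replicates 1 and 2 are compared. The number of lists below the 5th percentile, 1, ranged from 1 to 2 when each library was left out and was 3 against symbols above 0, where cumulus and fibroblast markers joined sperm transcripts, because that background is higher. Lists above the 95th percentile numbered 20 to 24 over all alternatives, against 24, with 21 without replicate 2 and 20 against symbols above 0. Shares of mitochondrially encoded genes ranged from 1.96 to 3.57% and of ribosomal proteins from 12.9 to 13.9% when each library was left out. Of 397 values under alternatives other than leaving out a library, 344 moved by less than the spread between libraries or, for counts, by under 1.5 times, and 53 moved further. Values with a library left out are not counted there, since most are means over libraries, which that cannot move by a whole SD. The correlation and the lists below the 5th percentile are not such means, and they moved as given above. The 1164 genes at least 2-fold from the other libraries in replicate 2 became 642 with a pseudocount of 5 and 255 at a mean of at least 50 TPM, fewer genes being counted, and 1018 to 1331 under the other settings. Depth is unknown, so low values cannot be told from sampling loss.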

Other observations

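Tests and alternatives in this part were all chosen after the values were seen. By gene counts, IVF replicate 2 stood farthest from the other libraries. Among 6978 genes with a mean of at least 5 TPM, 895 were at least 2-fold above and 269 at least 2-fold below the mean of replicates 1 and 3 on the log2(TPM + 1) scale. The corresponding counts were 394 and 538 for replicate 1, and 57 and 183 for replicate 3. By correlation replicates 1 and 2 were about equally far, with a mean Spearman coefficient with the other libraries of 0.916 and 0.915, against 0.938 for replicate 3. The median gene was 0.19 higher in replicate 2 (log2) and 60.3% of genes were higher, so counts of higher members below start from that share. Mitochondrially encoded genes were higher in 13 of 13 members, with a median log2 difference of 1.55, whereas nuclear oxidative phosphorylation genes lay at -0.29 (percentile 0.270 among random lists matched on mean TPM). Genome activation genes were higher in 23 of 26 members with a median of 0.62, pluripotency factors in 12 of 15 with 0.62 (percentile 98.7), and trophectoderm and endoderm genes in 6 of 9 with 0.95 (percentile 99.78). Lists outside development also lay above the 95th percentile: ribosome biogenesis (0.38, percentile 99.69), ribosomal proteins (0.11, 98.7), histone lysine demethylases (0.70, 98.2) and the proteasome (0.26, 95.5). For ribosomal proteins the median of 0.11 lay below the 0.19 of the median gene, and 43 of 75 members were higher. Their percentile is high because random lists matched on mean TPM lay lower still, with a central 95% of -0.258 to 0.093. Imprinted genes had a median of -0.33 (percentile 3.12), with 4 of 8 members higher. That median lay inside the central 95% of matched random lists, -0.362 to 0.734. Rows for tRNA, which polyA selection should leave out, were at least 2-fold higher in replicate 2 in 56.8% of 37 and lower in 16.2%, and took 0.0496, 0.144 and 0.0772% of TPM in replicates 1, 2 and 3. Rows with only a LOC identifier were at least 2-fold higher in 22.4% of 1152, against 10.5% of 5778 symbol rows.

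Outside the lists, symbols with large differences in replicate 2 are given as single genes. The protease inhibitors PI3 and SLPI were at 7.80, 93.0 and 4.83 TPM and 1.53, 29.5 and 8.14 TPM in replicates 1, 2 and 3, log2 differences of 3.71 and 2.67. GKN1 was at 7.14, 57.9 and 10.8 and the cytokine gene IL1A at 2.53, 20.9 and 3.55. Lower in replicate 2 were SIVA1, at 321, 44.4 and 125, and the methyltransferase gene GNMT, at 16.3, 1.18 and 9.17. CXCL1, with a log2 difference of -2.14, was high in replicate 3 alone, at 24.2, 16.8 and 245.

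Mitochondrial RNA displacing other transcripts was weighed for the distance of replicate 2. A larger share lowers every other gene alike, and the shares give a log2 shift of -0.0437, far under the 2-fold differences counted. Displacement therefore does not account for them. Earlier forms of this comparison, whose outcome the scaling itself decided, were replaced after values were seen. A further advanced genome activation may account for part of the pattern and stays open. That list's rise (percentile 99.99) is itself part of the pattern, so it is no separate support. The oocyte list, at percentile 6.14, did not fall past the 5th, and its members were mixed. In replicate 2, 12 of 33 were higher, GDF9 (67.5, 190 and 60.8 TPM in replicates 1, 2 and 3) and ZP2 (124, 353 and 124) included. Others were lower, such as MOS (493, 162 and 287). Cumulus or granulosa cells stay open too. Their summed markers were 0.971 of the mean of the other libraries, but 1.59 without GATM. Only 2 markers reached 10 TPM in a library. That marker comparison was made in 3 forms, of which the earlier were a difference and a ratio of sums carried by GATM. Depth, unknown here, stays untested. RNA quality and library preparation were not examined either, so the explanations weighed here are not the only ones possible.

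Of 13 core genes, which dividing cells use, that lie wholly inside another gene in the reference, 6 were listed at 0 in all 3 libraries. These were RPL27, PSMB6, NOP2, MED7, SUPT4H1 and AURKB. Wholly inside means here that overlapping genes, alone or together, cover the whole span. RPL27, for example, lies within IFI35. The remaining contained core genes were above 0 in a library, and 0 of 470 core genes not contained were at 0 in all. Among symbols in no fixed list, 261 of 590 genes wholly inside another gene were at 0 (44.2%) against 1299 of 14832 others (8.76%), a difference of 35.5 percentage points (Fisher's exact test, two-sided, p = 5.92e-108, over genes, which are not independent). Reads of contained genes left uncounted may account for such zeros, and lower true expression of contained genes was not separated from it. Of 28 list members at 0, 18 were not wholly inside another gene, so this covers part of them, and no biological explanation was tested.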
